A study of Homo sapiens with 4 samples.

How the data were processed

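The series measured which RNAs crosslink to RPS3A (eS1), a protein of the small ribosomal subunit, by single-end eCLIP in HEK293T, a human embryonic kidney cell line. Per the labels' protocols, cells stably carrying RPS3A with a FLAG-HA tag at its C terminus, delivered by lentivirus as a cloned open reading frame and kept under 2.5 µg/mL puromycin, were irradiated with UV light of 254 nm at 400 mJ/cm2. Lysates were sonicated, treated with RNase I and immunoprecipitated with an anti-HA antibody, and 2% of each lysate was set aside beforehand as its input. IP and input were both run on a protein gel, and RNA was recovered from the membrane between the size of the protein and 75 kDa above it, so the input is matched in size to the IP. The labels name 4 libraries, with 2 IP libraries (RPS3A IP) and 2 input libraries (RPS3A Input) from 2 stable cell lines described as biological replicates.

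What was analysed is 1 table of peaks for the whole series. Each peak carries a log2 fold enrichment of IP over input and a -log10 p-value, both computed by the authors and deposited in the table, per the file headers. Both are the authors' own values and were used to describe, rank, filter and compare peaks within that list. The genome build was GRCh38, per the submitters' processing notes. The aligner, the peak caller, the scaling of the libraries, the way in which the replicates were combined and the filters of the list were not given in the sources used here. All 866 peaks had a log2 fold and a -log10 p above 3, and no listed -log10 p exceeded 400, a value shared by 59 peaks, so p ranks nothing among those. The table gave 1 value per peak for the series, with no read counts and no values per library. The depth of the libraries is therefore unknown, no error across replicates could be computed, and no detection limit is given for genes without a peak.

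Gene names and transcript regions (coding sequence, UTR, proximal or distal intron, noncoding exon and others) were taken as the table gives them, in its column of genic regions, which differs from its column of assigned annotations for 15 of 866 peaks (11 of them tRNA in the second only); the boundary between proximal and distal introns was not given in the sources used here. Adjoining peaks shared a border, so start positions were read as counted from 0 and are printed counted from 1. Same-strand peaks at most 50 nt apart were merged into loci. A gene entry is a name as listed, which can join several overlapping genes. Of 481 single names in the table, 350 (72.8%) matched a RefSeq gene table of GRCh38, and 83 of the 131 unmatched names were lncRNA names of the form lnc-. Positions in that gene table were used because it has the same build. It gives no strand and no exons, so overlaps with it ignore strand. Near-identical copies such as 5S rRNA, tRNA, 7SK and U2 or U6 snRNA pseudogenes share sequence, and how the authors placed reads that match several copies is not given in the sources used here; entries of these families are therefore uncertain as to the copy.

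Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Fold enrichment was compared between gene lists and all other gene entries with a peak (highest log2 fold per entry), and between each region class and all other peaks, by two-sided permutation tests of the difference of medians with 100000 resamples. The smallest p such a test can give is 1.0e-05. Intervals of these differences came from 10000 bootstrap resamples. Benjamini-Hochberg adjustment was applied over the 4 lists with at least 5 entries and over the 7 region classes with at least 10 peaks. These tests compare items within one list, not conditions, and neighbouring peaks of a locus are not independent. For 21 lists, genes with and without a peak were compared with all annotated genes of the same biotypes by two-sided Fisher's exact tests, adjusted over those 21. This background ignores whether a gene is expressed in these cells. The tests and the intervals of these shares count near-identical copies of a family as independent genes. They are too strong where the same reads could be placed on several copies. Mitochondrial names did not match the gene table, and the microRNA list did not match the form in which the table names microRNAs, so the first was not tested, and the test of the second is void and not reported, although it counts among the 21.

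The 22 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule names RPS3A whether or not it has a peak, up to 5 rRNA entries, the 15 entries of highest log2 fold, the 10 entries with most peaks, and of each list with a peak the 4 members of highest log2 fold, with ties broken by the smaller p and then by name. The script at first broke ties in the number of peaks by fold instead; this was corrected to the rule after the values had been seen, and it put lnc-GCNT1-4 in the place of the LENG8-AS1 entry among the 10, both with 5 peaks and a -log10 p of 400, so that the name decided. Some entries that the rule names are not reported here. Overlaps by position with annotated rRNA, small RNA and pseudogene loci were added after the table had been seen. Comparisons of replicates were not run because the table holds no values per replicate; the position of peaks within transcripts and the base composition of peaks were not analysed because neither an exon annotation nor a genome sequence was used here.

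The permutation test was tested on simulated data made from the 373 gene entries. For a list of 17 entries it called 1% of 100 simulations with no shift, 65% with a shift of 1 log2 unit and 100% with a shift of 2. For 35 entries the shares were 5%, 92% and 100%, and for 14 entries 4%, 65% and 100%. Stricter fold and p thresholds, merged peaks, covered nucleotides, another priority of overlapping annotations, removal of multi-copy families, other values per gene and removal of intron peaks were tried as alternatives. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.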

Results

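The eCLIP experiment asked which RNAs crosslink to tagged RPS3A in HEK293T cells, by comparing 2 RPS3A IP libraries with 2 size-matched RPS3A Input libraries. The authors' deposited table listed 866 peaks, 454 on the plus and 412 on the minus strand, in 373 gene entries. The fold and p of each peak are the authors' values for the series as a whole; there are no replicate values, and the depth is unknown. Fold enrichment of IP over input ran from 8.18 to 2396, with a median of 74.8 (log2 6.23, interquartile range 5.39 to 7.42). Peaks were short, with a median width of 11 nt (interquartile range 7 to 20), and many adjoined one another. Merging peaks within 50 nt gave 407 loci with a median width of 26 nt (interquartile range 21 to 51), of which 300 held several peaks.

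Of the 15 entries of highest fold, all at a log2 fold of at least 9.16, 10 had a peak in an intron and 3 were rRNA entries. Introns held 67.0% of all peaks, so this count does not set introns apart. The highest value, a log2 fold of 11.23 (2396-fold), belonged to a distal intron of overlapping lncRNAs including LENG8-AS1 on chromosome 19 (22694810 to 22694896, GRCh38, minus strand, 5 peaks). VAMP4, which encodes a SNARE protein of the Golgi (ENSG00000117533.14), followed with a log2 fold of 10.25 in a distal intron (chromosome 1, 171713434 to 171713483). HAUS7, a subunit of the augmin complex of the mitotic spindle, reached 10.10 at a 3' splice site (chromosome X, 153462135 to 153462150) and had a locus in its coding sequence at 8.50.

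Other entries of this set were mostly introns of protein-coding genes with no shared function in the fixed lists. TMEM178B (chromosome 7) reached a log2 fold of 9.91 in a distal intron, RBM3, a cold-inducible RNA-binding protein, 9.44 in a proximal intron on chromosome X (48574742 to 48574765), and PID1 9.35 on chromosome 2. SLCO5A1, a member of the organic anion transporter family, reached 9.16. The antisense lncRNA entry SLC16A1-AS1|EFCAB14-AS1 reached 9.34. The lncRNA lnc-OR4F16-8 on chromosome 1 reached 9.29, and both of its loci lay between annotated nuclear pseudogenes of mitochondrial genes (MTND1P23, MTND2P28 and MTCO1P12). The microRNA entry hsa-mir-7641-2, at 9.95, overlapped the 5S pseudogene RNA5SP387 by position (chromosome 14, 75604217 to 75604265).

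ANKRD30BL had the most peaks, 21 in 7 loci of a noncoding distal intron on chromosome 2, with a highest log2 fold of 9.35. By position, 5 of these loci with 15 peaks lay inside an annotated 18S rRNA pseudogene of 1849 nt (132254347 to 132256195), at log2 folds of 6.71 to 8.03. HFM1, a meiotic DNA helicase, followed with 11 peaks in 5 loci on chromosome 1 and a highest log2 fold of 7.45. CRIM1, a transmembrane protein that binds BMPs, had 8 peaks (8.29), PHKB, a subunit of phosphorylase kinase, 7 peaks (7.89), and lnc-ZFHX3-10 7 peaks (7.29), of which 3 belong to the same merged locus as the peaks of tRNA-Lys-TTT-1-1. The entry RP5-972B16.2|TSPAN7 also had 7 peaks in 3 loci, at a highest log2 fold of 6.14 but a -log10 p of only 5.32. Some separate loci of 1 entry had equal or nearly equal values. In RP5-972B16.2|TSPAN7, 2 loci had a log2 fold of 5.74 and a -log10 p of 3.52, and in CRIM1 2 loci had log2 folds of 8.29 and 8.28. Equal values also crossed entries: DEPDC5 and NDUFA6-AS1 on chromosome 22 both had a log2 fold of 5.96 and a -log10 p of 6.24. Whether such loci are independent signals was not tested. These counts, and the comparisons of loci and of gene entries, may therefore hold 1 signal more than once. Of several entries with 5 peaks, the rule for ties named lnc-GCNT1-4, with 2 loci on chromosome 9 (76571764 to 76572045, plus strand) in a noncoding exon and at a splice site, a highest log2 fold of 8.67 and a -log10 p of 400.

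**Figure D1:**
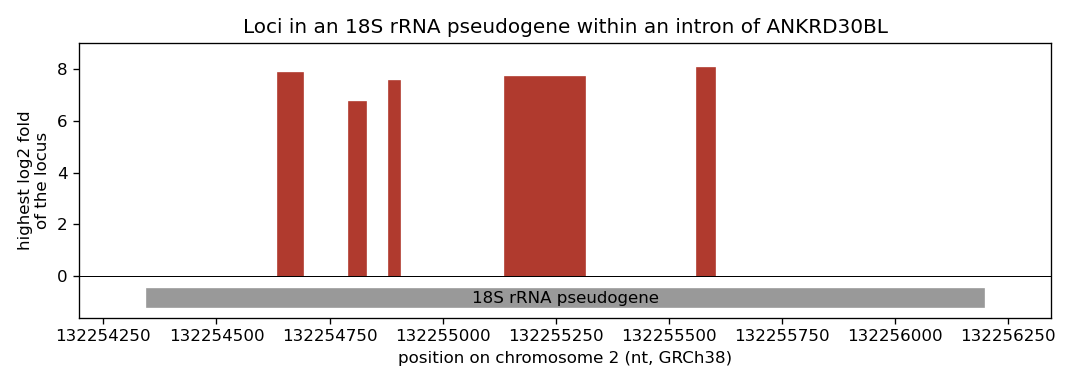
Map of 5 loci (red bars) inside the 18S rRNA pseudogene (grey bar) in an intron of ANKRD30BL; the x axis is the position on chromosome 2 in nt and the height of each bar is the highest log2 fold of IP over input in the locus. Bar heights run from 6.71 to 8.03.

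To see which parts of transcripts carried peaks, peaks were counted per region class as the authors' deposited table assigns it. Introns held 580 of 866 peaks (67.0%, 95% interval 63.7 to 70.1), most of them in distal introns of protein-coding genes (366 peaks, 42.3%, 38.9 to 45.6) and of noncoding genes (153 peaks, 17.7%, 15.2 to 20.4). Proximal introns of protein-coding genes held 57 peaks (6.58%). Exons of noncoding RNAs held 176 peaks (20.3%, 17.7 to 23.2) and tRNA genes 29 (3.35%; 40 by the table's other region column). Coding sequence and UTRs together held 53 peaks (6.12%, 4.62 to 7.93), with 31 in coding sequence, 18 in 3' UTRs and 4 in 5' UTRs. As a share of covered nucleotides, noncoding exons (33.7%) and distal introns (33.2%) were about level, since intron loci were narrow: a median of 24 nt (interquartile range 20 to 29) against 53 nt for noncoding exons.

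Fold enrichment differed between region classes. Among the 7 classes with at least 10 peaks, tRNA genes had the lowest median log2 fold, 4.34 against 6.34 in all other peaks, a difference of -1.99 (95% interval -2.47 to -1.42, permutation test, adjusted p = 3.5e-05), which was -1.27 between merged loci (11 tRNA loci, adjusted p = 0.0338). Noncoding exons were lower as well, 5.57 against 6.37, a difference of -0.79 (-1.17 to -0.52, permutation test, adjusted p = 3.5e-05). Distal introns of noncoding genes were higher, 6.63 against 6.14 (difference 0.49, 0.17 to 0.74, permutation test, adjusted p = 0.0039), although not when peaks of -log10 p below 5 were left out (adjusted p = 0.111). Distal introns of protein-coding genes differed by 0.21 (-0.06 to 0.55, permutation test, adjusted p = 0.057) and coding sequence by -0.67 (-1.85 to 0.19, adjusted p = 0.057), neither past the threshold. Distal introns passed it at a -log10 p of at least 5 (0.59, permutation test, adjusted p = 1.2e-04) and with the table's other region column (0.26, adjusted p = 0.0219). They did not pass it between merged loci (0.10, permutation test, adjusted p = 0.607) or at a log2 fold of at least 4 (0.12, adjusted p = 0.404). For proximal introns (difference 0.79, permutation test, adjusted p = 0.0114) and 3' UTRs (-1.32, adjusted p = 0.00773) the bootstrap intervals included 0, at -0.18 to 1.04 and -2.14 to 0.83. The difference of proximal introns was 0.09 between merged loci (permutation test, adjusted p = 0.771), and that of 3' UTRs was -0.12 at a log2 fold of at least 4 (adjusted p = 0.851) and -0.82 with the other region column (adjusted p = 0.104). That fold threshold acts on the value compared and left 13 peaks in 3' UTRs.

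**Figure D2:**
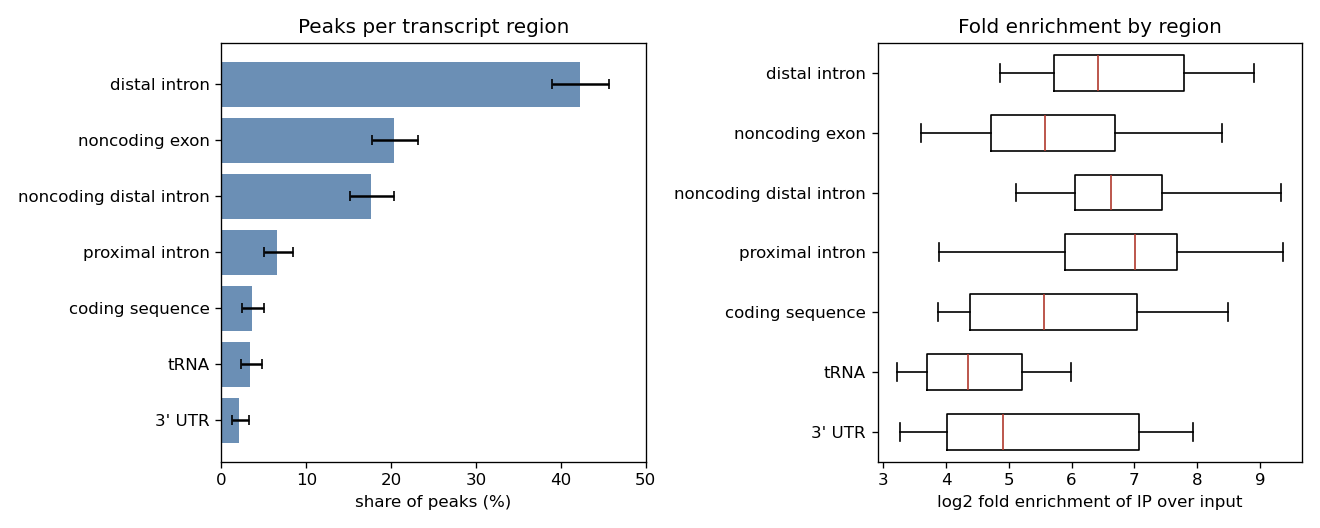
Left: share of peaks in percent per region class, with exact 95% intervals as error bars; right: log2 fold of IP over input per class, with the median as a red line, quartiles as the box and the 5th to 95th percentiles as whiskers. Distal introns hold the largest share (42.3%) and the median log2 fold of tRNA peaks is 4.34.

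The fixed lists asked which classes of RNA carried peaks. Ribosomal RNA entries were the largest class, with 76 peaks (8.78%, 95% interval 6.98 to 10.9) in 35 entries, of which 33 were 5S pseudogenes and the other two 5.8S pseudogenes. RNA5SP481 on chromosome 20 (32008384 to 32008442) reached a log2 fold of 10.08, RNA5SP429 on chromosome 16 reached 9.95, RNA5SP161 on chromosome 4 reached 9.47 over 9 peaks, RNA5SP389 reached 8.95 and RNA5SP370 8.39. Among the 5S pseudogene entries, 12 were at the highest -log10 p of 400. Of 565 annotated genes and pseudogenes of the list, 35 (6.19%, 4.35 to 8.51) had a peak, against 36 of 15104 other genes of the same biotypes (0.238%, Fisher's exact test, adjusted p = 1.5e-30). Near-identical copies were counted as independent genes, so this p and interval overstate the evidence if copies shared reads. The median log2 fold per rRNA entry was 6.49 against 6.08 in all other entries, a difference of 0.41 that did not pass the test (-1.22 to 0.90, permutation test, adjusted p = 0.265). Against entries with peaks outside introns the difference was 1.05 (permutation test, adjusted p = 0.00896), and with the median over the peaks of each entry it was -0.0846 (adjusted p = 0.755). By -log10 p the rRNA entries were higher than the others by 47.5 (permutation test, adjusted p = 4.0e-05).

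Transfer RNA genes carried 40 peaks (4.62%, 3.32 to 6.24) in 17 entries, with low fold but often small p. The highest were tRNA-Ser-AGA-2-6 (log2 fold 6.29, chromosome 17, 8226593 to 8226659), tRNA-Asp-GTC-2-11 (6.23, at a -log10 p of 400), tRNA-Lys-TTT-1-1 (5.82) and tRNA-Gly-GCC-2-4 (5.43). Their median log2 fold was 4.28 against 6.13 in all other entries, a difference of -1.85 (-2.26 to -0.83, permutation test, adjusted p = 6.8e-04). This call was lost at a log2 fold of at least 4 (-1.003, permutation test, adjusted p = 0.184) and without intron peaks (-1.04, adjusted p = 0.0541). The fold threshold acts on the value compared and left 11 of the 17 entries, so its result alone says little. By -log10 p the tRNA entries were higher than the others by 25.9 (permutation test, adjusted p = 0.00848). Of 522 annotated members, 14 (2.68%) had a peak, against 342 of 53943 other genes (0.634%, Fisher's exact test with copies counted as independent, adjusted p = 1.2e-04). This background holds every biotype that any member of the list has. With only the main biotypes of the list, a setting chosen after the data were seen, the counts were 14 of 519 and 71 of 15560 (Fisher's exact test, adjusted p = 5.4e-06).

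Spliceosomal snRNA entries carried 23 peaks in 14 entries, nearly all named as pseudogenes, led by RNU6-4P (log2 fold 7.96, chromosome 3), RNU2-39P (7.47), RNU4-82P (6.69) and RNU2-22P|LINC00471 (6.002). They were not past the threshold against the background (14 of 1862 genes, 0.752%, Fisher's exact test, adjusted p = 0.117) or in fold by the test (difference -0.48, permutation test, adjusted p = 0.265), although the bootstrap interval of -1.02 to -0.04 excluded 0. The list of 7SK, Y and other small structured RNAs carried 24 peaks in 15 entries, all of them 7SK pseudogenes or Y RNAs. These were led by RN7SKP71|lnc-TRAFD1-4 (7.05), the 2 entries named Y_RNA (6.88 and 6.71) and lnc-ZCCHC17-11|RN7SKP91 (6.57). Its genes had peaks more often than the background (13 of 1068, 1.22% against 0.369%, Fisher's exact test with copies counted as independent, adjusted p = 0.00332). The fold difference was -0.47 (-1.03 to 0.36, permutation test, adjusted p = 0.265).

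**Figure D3:**
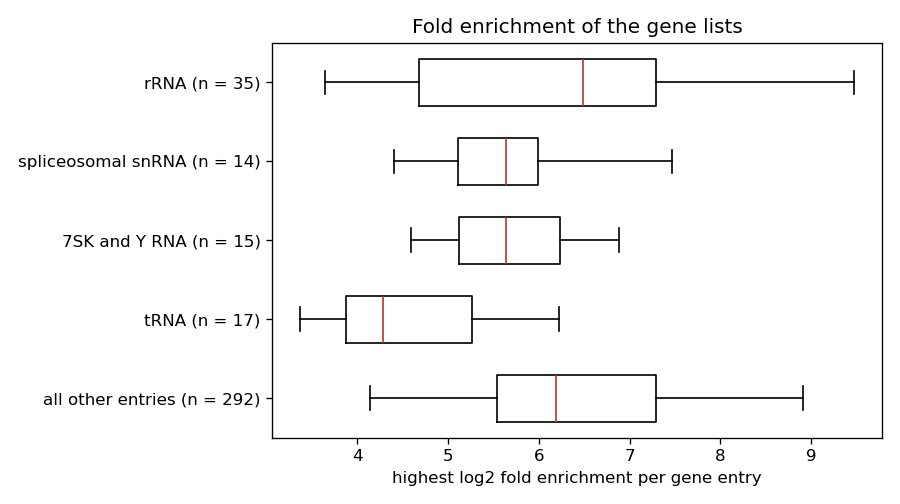
Highest log2 fold of IP over input per gene entry (x axis) for the 4 tested lists and for all other entries, with the median as a red line, quartiles as the box and the 5th to 95th percentiles as whiskers. The median is 4.28 for tRNA, the lowest of the 5 groups, and 6.49 for rRNA.

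The H/ACA box list carried 6 peaks and the C/D box list 2, neither past the threshold against the background (Fisher's exact test, adjusted p = 0.293 and 1). Both H/ACA entries were copies of U17, which acts in 18S rRNA processing: SNORA73B at a log2 fold of 4.86 and SNHG3|SNORA73A at 4.48 with a -log10 p of 400. The C/D box entries were SNORD62B (6.37) and SNORD3C (4.14), a copy of U3, which also acts in 18S processing. Mitochondrial tRNAs MT-TC and MT-TL1 reached 7.40 and 4.19. PTCD3, a mitochondrial ribosome protein and snoRNA host, had an intron locus at 8.01. CCT3, a chaperonin subunit, and TUBA1C, an alpha tubulin, had 1 peak each in coding sequence at 3.86 and 3.46. Peaks were listed for no member of 12 lists: small Cajal body RNAs, replication-dependent histones, microRNAs (the table's own microRNA entry has another form of name), small-subunit ribosomal proteins, translation factors, non-ribosomal 5' TOP mRNAs, ribosome biogenesis factors, glycolytic enzymes, mitochondrial ribosomal proteins named MRPL or MRPS (which leaves out PTCD3), proteasome subunits, hnRNP and SR proteins, and nuclear lncRNAs. The table lists only regions past its thresholds, so a missing peak does not show that an RNA was not bound.

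RPS3A itself (chromosome 4, 151099628 to 151104642) had 0 peaks, by name and by position.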

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

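No paired analysis was possible because the table holds 1 fold and 1 p per peak for the series, although IP and input share replicate numbers 1 and 2; leaving out a replicate was not run for the same reason. A minimum overlap of each peak with its feature, other windows around codons and splice sites and another flank distance were not run, for lack of an exon annotation and a sequence. The merging distances of 0 and 200 nt, the narrower background and the other region column were chosen after seeing the data, as were the stricter thresholds for overlaps by position. Of 147 recomputed values, 115 kept their direction, their side of the threshold or their interval. The 866 peaks became 407 loci within 50 nt, 473 within 0 nt and 399 within 200 nt. By covered nucleotides, distal introns held 33.2%, noncoding exons 33.7% (23.3% of merged loci), noncoding distal introns 13.9%, proximal introns 4.81% and 3' UTRs 3.88%. At a log2 fold of at least 4, the share of tRNA region peaks was 2.22% and of the tRNA list 2.59%, and the fold differences were -1.003 for the tRNA list and -0.12 for 3' UTRs. Without multi-copy families the shares of the rRNA, tRNA, spliceosomal and small structured RNA lists were 0, by construction. With -log10 p in place of fold, the differences were 47.5 for rRNA, 25.9 for tRNA (reversed) and 1.36 for snRNA (reversed, not called). Without intron peaks they were 1.05 for rRNA, -1.04 for tRNA, 0.11 for snRNA and 0.10 for small structured RNAs, the last pair reversed and not called. With the median per gene, rRNA gave -0.0846 (reversed, not called). At a -log10 p of at least 5, distal introns gave 0.59 and noncoding distal introns 0.34; merged proximal introns gave 0.0856. With the region of the assigned annotation, distal introns gave 0.26 and passed the threshold, and 3' UTRs gave -0.82 and did not. The cause was not tested. Putting coding sequence before small RNA exons moved 0 peaks, so it tests nothing and is not counted above. Depth is unknown, so what it limits cannot be given.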

Other observations

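Other annotated RNAs lay under peaks that the authors' deposited table names after a host gene. By position, 110 of 407 loci (27.0%, 95% interval 22.8 to 31.6) overlapped annotated rRNA, tRNA, snRNA, 7SK, snoRNA, mitochondrial or RPS3A pseudogene loci, and 13 of these were listed as introns. Ribosomal RNA genes and pseudogenes held 45 loci (11.1%, 8.18 to 14.5). Of these, 9 lay in 18S or 28S sequence, all listed as introns: 5 in the 18S pseudogene within ANKRD30BL, 1 in RNA28SN2 (chromosome 21, 8216304 to 8216403, log2 fold 5.82), 2 in RNA28SN3 (chromosome 21, 8397611 to 8397669 and 8397937 to 8397984, 7.32 and 6.35) and 1 in a 28S pseudogene within TEX101 on chromosome 19 (6.35). Among small RNAs, SNORD118 (U8), which acts in 28S and 5.8S processing, lay under a locus listed as the 3' UTR of TMEM107 (3.50), and the U7 snRNA RNU7-1, which acts in histone mRNA 3' end formation, under one listed as the 5' UTR of C12orf57 (4.69). These overlaps and the genes named in this part, other than those of the report, were chosen after their values were seen.

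RPS3A pseudogenes carried peaks although RPS3A did not. There were 8 loci in 7 of 54 annotated RPS3A pseudogenes (13.0%, 5.37 to 24.9): RPS3AP5, RPS3AP6, RPS3AP7, RPS3AP13, RPS3AP20, RPS3AP43 and RPS3AP49, at log2 folds of 4.47 to 5.63. RPS3AP7 on chromosome 1 (226438538 to 226439394) had 2 loci. All were called noncoding exons, and the count stayed at 7 at a log2 fold of at least 4 and at a -log10 p of at least 5.

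The following weighs 3 patterns; the tests of gene length, of position along 5S copies and of width at like -log10 p were set before their results were seen (the last after the unpaired widths were known, and with its structured RNA loci narrowed after its result), and the others after.

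A candidate explanation for the RPS3A pseudogenes is that reads of spliced RPS3A transcripts were placed on intronless copies. Pseudogenes of other ribosomal proteins had a locus in 0 of 1940 cases, which argues against signal on ribosomal protein pseudogenes in general, since the upper 95% limit for those is 0.190%, with copies counted as independent. Whether reads of spliced transcripts account for the 7 pseudogenes stays open, since this family was singled out because it carried peaks and the sequences were not analysed here. The source may be the tagged construct, which is an intronless reading frame, or the endogenous mRNA; the table cannot separate them. No biological explanation was tested.

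Most peaks lay in introns, in loci of a median 24 nt. The 188 loci in introns of protein-coding genes with a known length, outside the annotated RNAs above, had a median host gene length of 163084 nt, inside the central 95% of 10000 draws of genes in proportion to length (136281 to 217765) and far above the median of 24140 nt (upper limit of their central 95% 31487) in draws that ignored length. Placement in proportion to gene length may therefore be enough to give these hosts. The test cannot tell whether the loci came from short reads placed by chance, precursor RNA at large or RNA bound in introns. The draws used all 20050 protein-coding genes, expressed or not, and the sequences were not analysed here. Genes of the strongly expressed lists held 0.532% of these loci (1 locus, 0.0135 to 2.93) against 0.861% of gene length, and this is too few to decide whether precursor RNA of strongly expressed genes contributed. All 190 intron loci together had a median width of 24 nt (interquartile range 20 to 28). The 98 loci on structured RNAs (RPS3A pseudogenes and nuclear copies of mitochondrial genes left out) had 54.5 nt (41.25 to 62.75). The difference of medians was -30.5 nt (95% interval -34 to -26). It was -32 nt (-36 to -19.5) when each intron locus was paired with the structured RNA locus of nearest -log10 p. For the intron loci as a set, this was the outcome set as evidence against fragments of the same length as those on structured RNAs. The pairing drew on 55 distinct structured RNA loci, and a like -log10 p need not mean a like number of reads, which is unknown. Intron loci that are narrow for want of reads are therefore not excluded, and width does not decide the question. Some intron loci, such as those of VAMP4 (50 nt) and PID1 (57 nt), were as wide as structured RNA loci. Peak calling on short genes may also shape width.

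On 5S pseudogenes, 34 loci lay on 34 of 510 copies, and 0 of 17 active 5S genes had a locus. With so few active genes, and with the placement of reads that match several copies unknown, these counts do not set pseudogenes apart from active genes. On the 23 copies between 100 and 140 nt long, 17 loci covered position 45 from the 5' end, with the strand taken from the peak. The interquartile range of their midpoints was 26 nt (bootstrap interval 7.75 to 47.5) against a median of 33 nt in simulated random placements (20 to 46.75, one-sided p from these placements = 0.160). Whether a fixed part of 5S is bound stays open: the observed range lay within that of random placements, the outcome set beforehand as evidence against it, but its own interval is too wide to exclude it, a criterion added after the value was seen. No biological explanation was tested.

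Of 386 loci below the highest -log10 p, 236 (61.1%) had a -log10 p shared exactly with another locus, and 14 loci shared the value 6.70.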
